A study of Homo sapiens with 8 samples.

How the data were processed

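The data were 8 chromatin immunoprecipitation sequencing (ChIP-seq) libraries for histone H3 trimethylated at lysine 4 (H3K4me3) from MM1S cells, an established human multiple myeloma line. Per the labels, 5 libraries came from cells given the vehicle DMSO and 3 from cells given 50 uM KDM5-C70 for 7 days. Per the labels' protocols, crosslinking took 8 minutes in formaldehyde at 1%, chromatin was sonicated, and 1 ug of antibody was used for the precipitation. Trim Galore 0.40, Bowtie 1.1.2, MACS2 2.1.0 and HOMER 4.8 are named in the submitters' processing notes, with GRCh37 as the genome build. Their settings, the role of HOMER and any control library are not given in the sources used here.

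The authors deposited 1 list of called regions per library, so regions were called in each library and not on pooled samples. Each list has 15 columns and no header. Its positions are whole numbers of base pairs, and each deposited region also carries a number of inner blocks with their sizes and starts. Blocks of 1 bp, which only mark the ends of a region, were left out, and the remaining blocks are called inner segments here. The lists also hold, as deposited, a display score, a fold enrichment (a ratio), and the -log10 of a p-value and of a q-value for each region. These are the authors' values for each region and were used to filter or rank regions within a list, and the median fold enrichment of each list is given once, as a limit. They followed the regions poorly. Over the 13729 merged regions called in all 8 libraries, Spearman's rho of the -log10 q-value between 2 libraries lay between 0.058 and 0.26, while that of the called width lay between 0.64 and 0.93. Within a library, rho between the -log10 p-value and the width lay between 0.092 and 0.12. Alternatives that use these values therefore tend to keep different regions in different libraries. Further lists of equal length were made by keeping the widest regions. A limit of 5 on the -log10 q-value also acted differently in the 2 groups. In every KDM5-C70 library it passed regions without an inner segment more often than regions with one. In every DMSO library it passed them less often. No read counts or totals were used, so the depth of each library is unknown and no counting interval can be given for a library.

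Regions on chromosomes 1 to 22 and X were analysed. Positions are given as counted from 1 on GRCh37. The lists were joined into merged regions wherever regions overlapped by at least 1 bp, which gave 50523 merged regions. The called width of a library in a merged region is the number of called bases it has there. Overlap of 2 libraries is the Jaccard index of their called bases, which is the bases called in both over the bases called in either. Single values per library were compared with the 2-sided exact permutation test over the 56 splits of 8 libraries into 5 and 3, in which the smaller tail is doubled and the smallest p is 0.0357. The difference of the Jaccard index within and between groups was tested 1-sided over the same splits. Called widths were compared with limma 3.58.1 in R 4.3.3 on log2 called bases over the regions called in all 8 libraries, with a variance trend, without centring of libraries, 2-sided, and with Benjamini-Hochberg adjustment at 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A pseudocount of 200 bp was used only in the alternative that includes regions called in at least 2 libraries of each group.

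Merging, called widths and the Jaccard index were tested on simulated intervals. The limma step was tested on simulated widths for the 13729 regions, with 200 regions changed. Without a term for the set of libraries it recovered 16% of 100 regions changed by 1 on the log2 scale and 74% of 100 changed by 2, with 1 false call. With that term it recovered 72% and 96%, with 10 false calls. The simulated noise was independent for each region and library, with no shift in width shared across a library. Fits with centring were not simulated. These rates may therefore not hold for the fits to the data.

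Groups, tests, alternatives and the rule for named regions were fixed before the data were examined. The rule took the 10 regions with the smallest p in each direction among those whose 3 KDM5-C70 values do not overlap the 5 DMSO values if none passed the threshold, the 5 widest merged regions by mean over the 8 libraries, and up to 5 regions called in every library of 1 group and in none of the other. Results by gene, promoter and gene list had also been fixed, but the gene table used here is of GRCh38.p14, so no gene was assigned to a GRCh37 region and regions are named by position. Alternatives covered stricter lists (-log10 q-value of at least 5), lists of equal length, inner segments only, joining regions within 1000 bp, other width limits, centring, no variance trend, the replicate number as a block, and leaving out each library.

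Added after the data were examined were the inner share of called sequence, a split of the libraries into DMSO 1, DMSO 2 and KDM5-C70 1 against the other 5, and all fits that use that split. The split was read from the overlap of the lists, and the labels name no batch. Region names inside the lists carry the numbers 4, 5 and 6 for DMSO 3, 4 and 5 and the numbers of the labels for the other 5 libraries, so the block by replicate number, which used the labels, pairs DMSO 3 with a library whose names carry another number. Group labels were then permuted within the 2 sets, which allows 30 arrangements. That p counts arrangements with an absolute difference at least as large, so its smallest value is 0.0333, and with the smaller tail doubled it would be 0.0667. The replicates are separate samples in the labels, which do not say that they came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.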

Results

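H3K4me3, a histone mark found mainly at active promoters, was mapped in MM1S multiple myeloma cells given 50 uM KDM5-C70 for 7 days, or given the vehicle DMSO, for which the labels state no time. KDM5-C70 inhibits the KDM5 family of histone demethylases, which remove methyl groups from this residue, and the comparison asks how the regions carrying the mark differ between treated and control cells. There were 5 DMSO libraries and 3 KDM5-C70 libraries, each with its own list of called regions. The DMSO lists held 20998, 15323, 32376, 30363 and 28195 regions for replicates 1 to 5. The KDM5-C70 lists held 17977, 32133 and 37948 regions for replicates 1 to 3. Together they formed 50523 merged regions, of which 13729 (27.2%) were called in all 8 libraries and 16023 in 1 library. The depth of each library is unknown, so a region absent from a list is one that was not called, which does not show that the mark was absent there.

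Across all 8 libraries the lists did not separate by treatment, except when cut to stricter lists of very different lengths. The mean Jaccard index of called bases was 0.539 between libraries of the same group and 0.519 between libraries of different groups, a difference of 0.0205 (1-sided exact permutation p = 0.357, 56 splits), which rose to 0.158 with stricter lists (1-sided exact permutation p = 0.0179). Those hold 3028 to 7036 regions in KDM5-C70 and 6394 to 19917 in DMSO libraries, and list length alone can move the index. With lists of equal length the difference was 0.0198 (1-sided exact permutation p = 0.232), with the widest regions 0.0354 (p = 0.161) and with inner segments 0.0287 (p = 0.286). DMSO 1, DMSO 2 and KDM5-C70 1 overlapped each other at 0.666 to 0.677, and DMSO 3, 4 and 5 with KDM5-C70 2 and 3 at 0.56 to 0.734. Between these 2 sets the index lay between 0.309 and 0.543. The 5 libraries shared 5362 merged regions that none of the other 3 had, and the reverse count was 180. Within the 5 libraries, those of the same group overlapped more (mean 0.693) than those of different groups (mean 0.591), and this difference of 0.102 was the highest of the 10 ways to pick 2 of the 5. The 3 DMSO pairs overlapped at 0.7 to 0.734, and the 1 KDM5-C70 pair at 0.626. That is little above the 0.606 to 0.618 of KDM5-C70 2 with DMSO 3, 4 and 5. KDM5-C70 3 overlapped those DMSO libraries at 0.56 to 0.583. Values within these sets are given below for the measures per library and the counts of regions. Named regions are mostly given as pooled means, whose SD includes any difference between the sets. The sets were recognised only from the data.

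**Figure D1:**
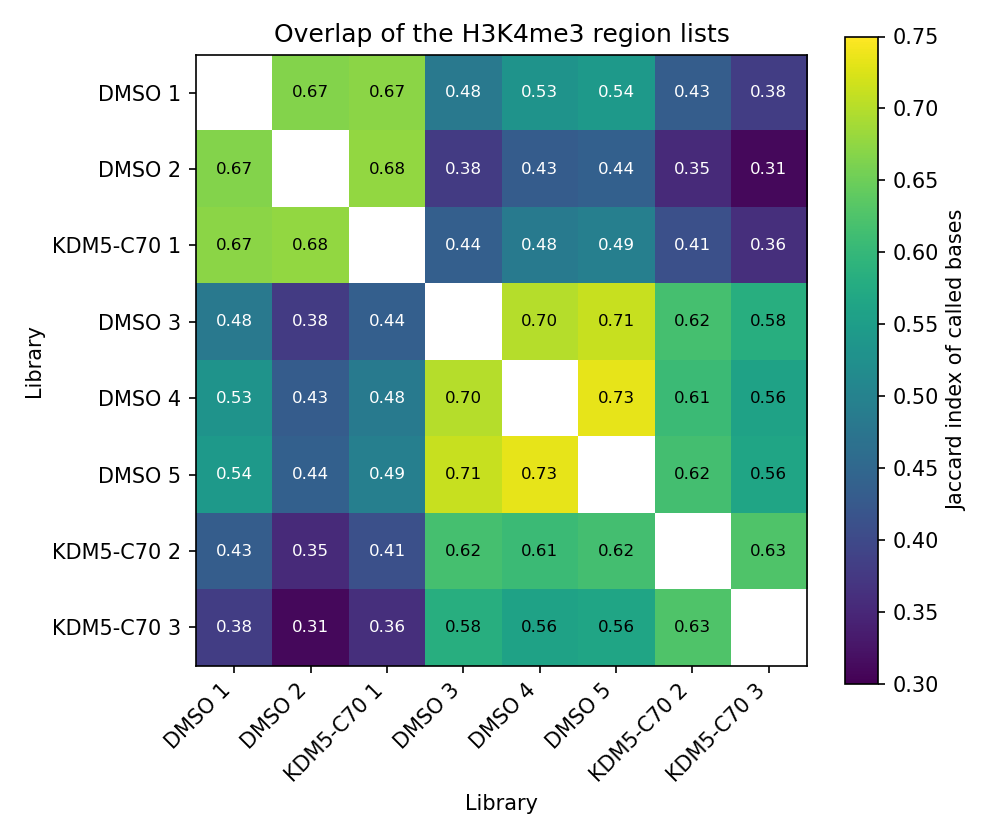
Jaccard index of called bases for each pair of the 8 libraries, with libraries ordered by the 2 sets described in the text and the colour scale running from low (dark) to high (light). DMSO 1, DMSO 2 and KDM5-C70 1 reach at least 0.666 with each other and at most 0.543 with the other 5.

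Called regions covered 28.2 ± 11.3 Mb (SD, n = 3) in KDM5-C70 libraries and 23.7 ± 7.99 Mb (SD, n = 5) in DMSO libraries, a difference smaller than the spread (exact permutation p = 0.464). The number of regions was 29353 ± 10270 (SD, n = 3) with KDM5-C70 and 25451 ± 7107 (SD, n = 5) with DMSO (exact permutation p = 0.536). The median region width was 813 ± 43.9 bp (SD, n = 3) and 799 ± 42.2 bp (SD, n = 5) in the same order (exact permutation p = 0.607). Broad regions of at least 4 kb were few, at 7.33 ± 2.08 (SD, n = 3) with KDM5-C70 and 12 ± 8.09 (SD, n = 5) with DMSO (exact permutation p = 0.393), and no library had a region of 10 kb. Without DMSO 3, which had 26 broad regions, their difference of -4.67 shrank to -1.17. When labels were permuted within the 2 sets, 3 of these 4 measures did not differ by more than the spread either. By absolute differences the exact permutation p was 0.3 for the number, 0.667 for the median width and 0.167 for the covered length. With the smaller tail doubled it was 0.333, 0.667 and 0.2. For the broad regions the exact permutation p was 0.233 by absolute differences and 0.0667 with the smaller tail doubled. The latter is the smallest that rule allows, so the 2 rules do not give the same reading. Stricter lists turned 3 of the 4 measures, with KDM5-C70 minus DMSO at -9938 regions and -10.6 Mb (exact permutation p = 0.0714 for both, and 0.0333 within sets by absolute differences) and at -168 bp of median width (exact permutation p = 0.0357), and took the broad regions to -8.80 (exact permutation p = 0.0357). In the 5 libraries, KDM5-C70 2 and 3 covered 32.7 and 36.7 Mb, and DMSO 3, 4 and 5 covered 32.3, 27.7 and 27.5 Mb. In the other 3, KDM5-C70 1 covered 15.4 Mb, between DMSO 1 with 17.8 Mb and DMSO 2 with 12.9 Mb.

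Inner segments took a smaller share of the called sequence with KDM5-C70. They made up 57.7 ± 1.07% (SD, n = 3) of called sequence in KDM5-C70 libraries and 70.7 ± 3.39% (SD, n = 5) in DMSO libraries, a difference of -13.0 percentage points (exact permutation p = 0.0357, the smallest that 56 splits allow). The 3 KDM5-C70 libraries lay at 58.4, 58.2 and 56.5%, below all 5 DMSO libraries at 68.2, 69.3, 76.3, 68.3 and 71.7%. The difference was present in both sets of libraries, with 58.4% in KDM5-C70 1 against a mean of 68.8% in DMSO 1 and 2, and a mean of 57.3% in KDM5-C70 2 and 3 against 72.1% in DMSO 3, 4 and 5 (exact permutation within sets, p = 0.0333 by absolute differences, the smallest that 30 arrangements allow, and 0.0667 with the smaller tail doubled). Over only the regions called in all 8 libraries the shares were 65.7 ± 3.90% (SD, n = 3) and 78.1 ± 5.17% (SD, n = 5), with the same exact permutation p of 0.0357. There the groups nearly met, with the highest KDM5-C70 share at 69.8% and the lowest DMSO share at 70.7%. The inner share was chosen as a measure after the data were examined. The median width of single inner segments, an alternative fixed beforehand, differed by -88.4 bp between KDM5-C70 and DMSO (exact permutation p = 0.0357). Their number differed by 5281 (exact permutation p = 0.5) and their covered length by -0.64 Mb (exact permutation p = 0.929). Single segments were thus shorter, while the total length of inner segments did not differ beyond the spread.

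**Figure D2:**
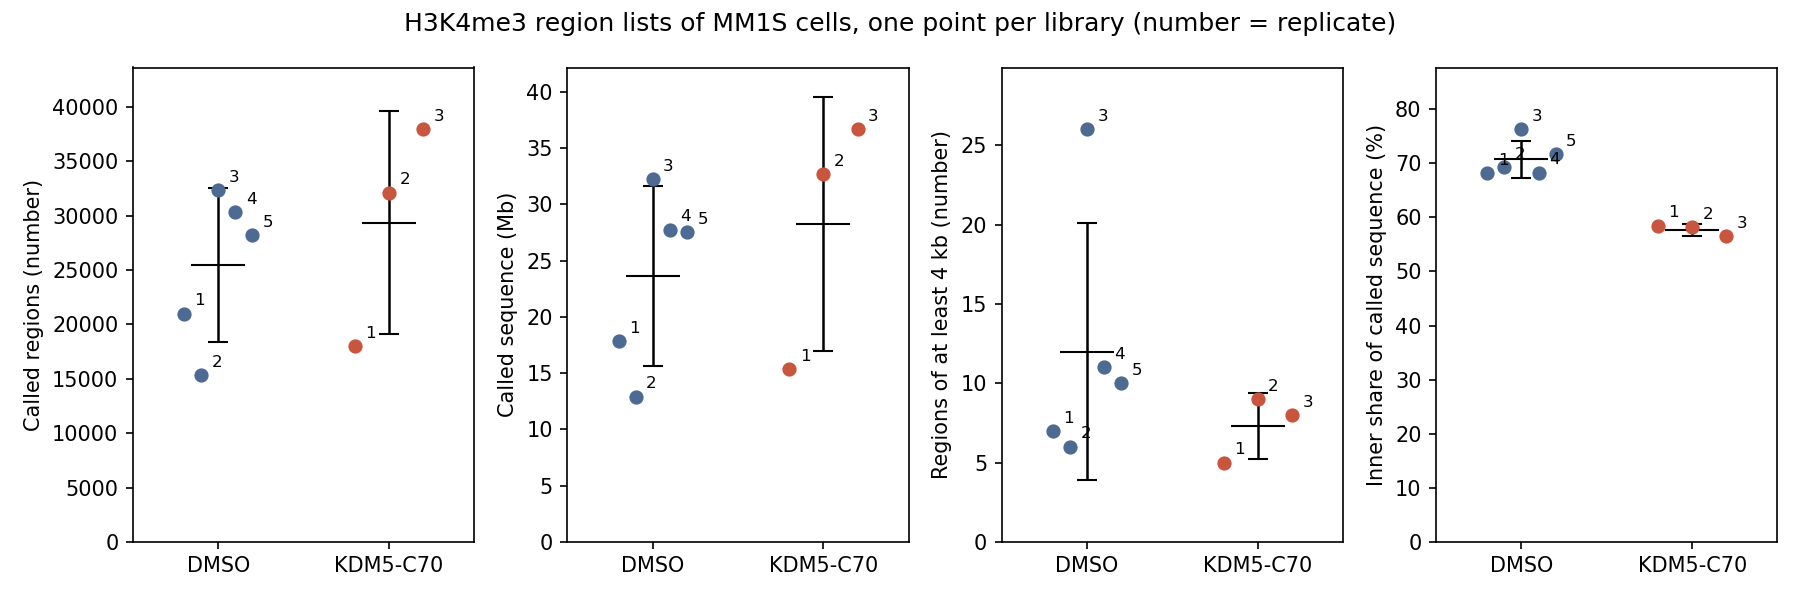
Number of called regions, called sequence in Mb, number of regions of at least 4 kb and inner share of called sequence in percent, with 1 point per library labelled by its replicate number, and the mean and SD of each group as horizontal lines and bars. The groups overlap in the number of regions, the called sequence and the broad regions, while the inner share of the 3 KDM5-C70 libraries lies at or below 58.4% and that of the 5 DMSO libraries at or above 68.2%.

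Among the regions called in all 8 libraries, a few regions were called much narrower in every KDM5-C70 library, although none passed the threshold of the fixed test. With the replicate number as a block, an alternative fixed beforehand that leaves out DMSO 4 and 5, 3 of them passed. They lay on chromosome 5 (88176066 to 88180395, limma adjusted p = 0.0024), chromosome 16 (79631402 to 79635998, limma adjusted p = 0.0105) and chromosome X (39953325 to 39957156, limma adjusted p = 0.0168). The numbers share no clear pairing, and number 2 pairs DMSO 2 with KDM5-C70 2 of the other set, so the difference between the sets enters this fit. Its median log2 change was 0.265, against 0.141 in the fixed test. On chromosome 16, the region from 79631402 to 79635998 had a called width of 880 ± 192 bp (SD, n = 3) with KDM5-C70 and 2680 ± 697 bp (SD, n = 5) with DMSO, a log2 change of -1.60 (SE 0.24). In KDM5-C70 3 it held no inner segment. On chromosome 4, the region from 74964522 to 74965281 had 156 ± 12.3 bp against 570 ± 118 bp (SD, n = 3 and 5), and that on chromosome 5 from 88176066 to 88180395 had 703 ± 396 bp against 2386 ± 685 bp. The shortest region in every list was 146 bp. The KDM5-C70 values on chromosome 4 (146 to 170 bp) lie near that floor, which limits their mean and SD. KDM5-C70 1 was also at 146 bp in the region on chromosome X from 133506922 to 133509038. On chromosome 2, the region from 43451304 to 43454922 had 1912 ± 251 bp against 3418 ± 204 bp, and 1 of the 4 regions called in every DMSO library and in no KDM5-C70 library lay close by, from 43445743 to 43447459. The others of the 10 narrower regions lay on chromosome 14 (100704154 to 100707164), chromosome 12 (104322987 to 104325765 and 89744322 to 89746184), chromosome 6 (157098270 to 157101488) and chromosome X (39953325 to 39957156 and 133506922 to 133509038). Their log2 changes lay between -0.89 and -2.26.

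**Figure D3:**
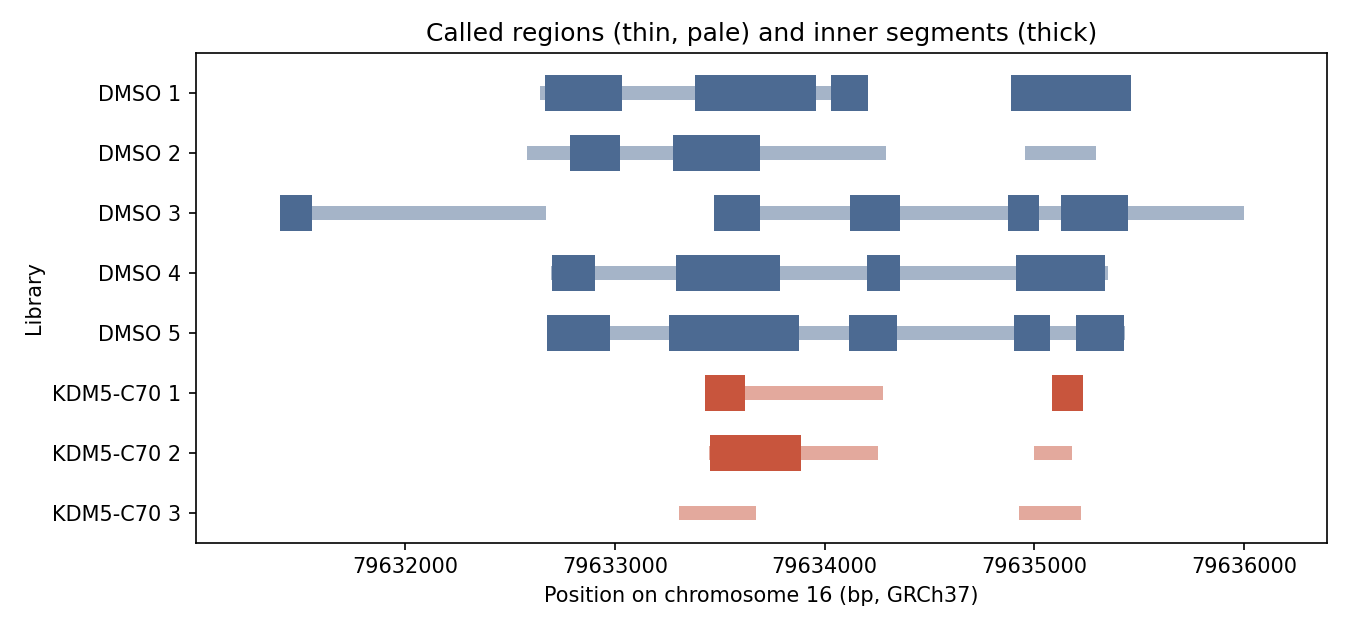
Called regions (thin, pale bars) and inner segments (thick bars) of each library on chromosome 16 between 79631402 and 79635998, with position in bp on GRCh37 along the horizontal axis and 1 line per library. The 5 DMSO libraries have 2054 to 3798 called bases there and the 3 KDM5-C70 libraries 659 to 998.

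Other regions were wider in every KDM5-C70 library, and the 10 of them with the smallest p did not pass the threshold either. The region on chromosome 2 from 241506222 to 241509196 had a called width of 2804 ± 118 bp (SD, n = 3) with KDM5-C70 and 1783 ± 282 bp (SD, n = 5) with DMSO, a log2 change of 0.67 (SE 0.17). On chromosome 17, the region from 3865549 to 3868949 had 2817 ± 524 bp against 1687 ± 241 bp, and that on chromosome 3 from 160166052 to 160168176 had 1765 ± 458 bp against 837 ± 286 bp. The region on chromosome X from 48931120 to 48932288 had the highest log2 change of the 10, at 1.35 (SE 0.37), with 822 ± 107 bp against 341 ± 136 bp. The others lay on chromosome 1 (226297254 to 226300263, 156718555 to 156722401 and 26560664 to 26562593), chromosome 15 (45926564 to 45929441), chromosome 11 (63741579 to 63743421) and chromosome 16 (30568395 to 30570329), with log2 changes between 0.61 and 0.73.

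**Figure D4:**
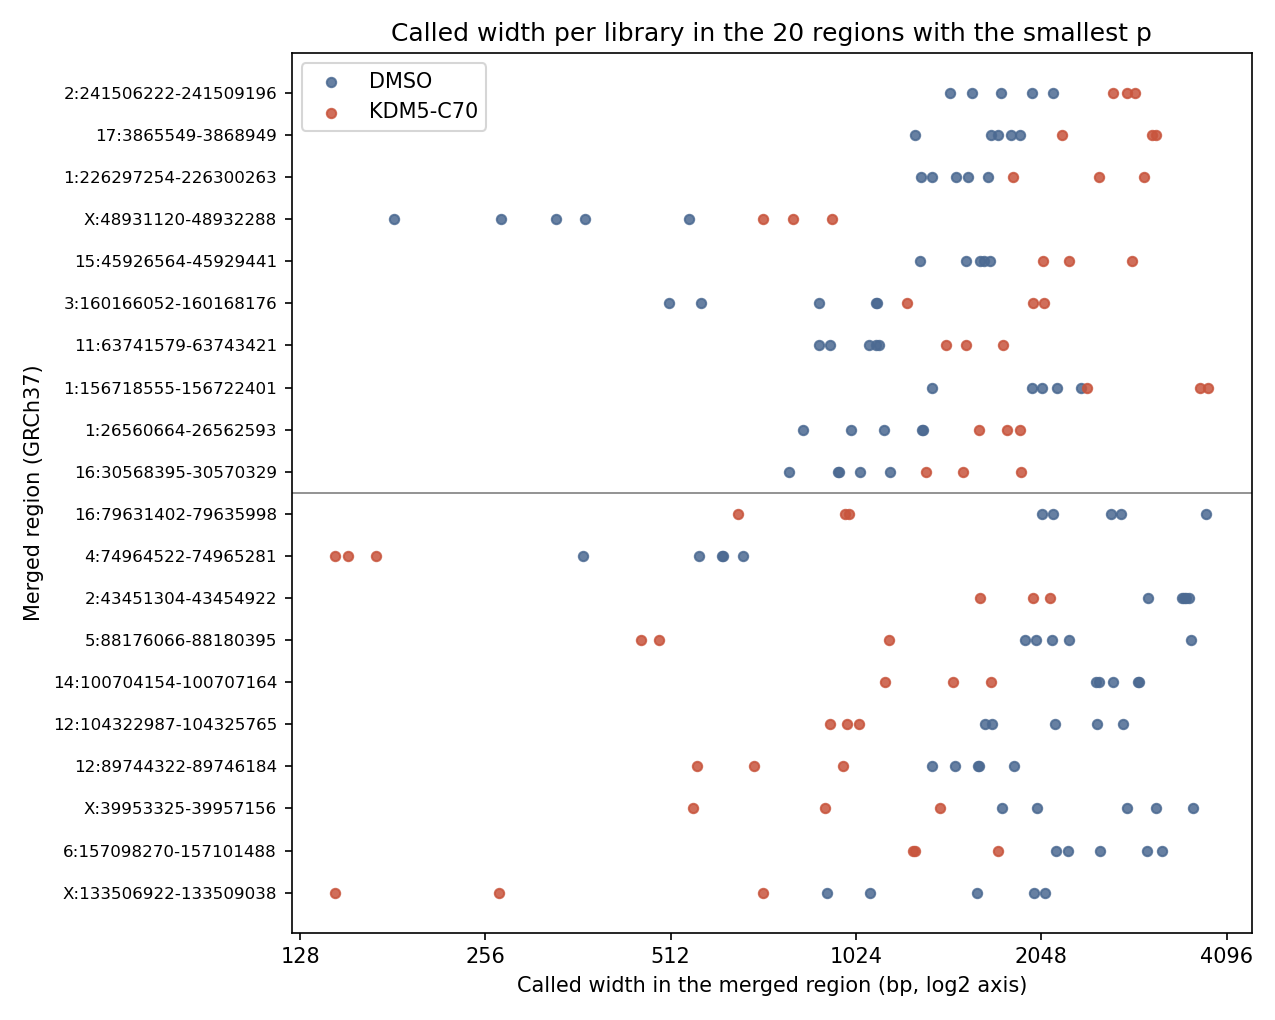
Called width per library in bp, on a log2 axis, in the 10 regions wider (above the line) and the 10 narrower (below the line) with KDM5-C70 that had the smallest p among regions whose groups do not overlap, with 1 point per library. In the region on chromosome 4 the 3 KDM5-C70 libraries have 146 to 170 called bases and the 5 DMSO libraries 369 to 670. The shortest region in every list is 146 bp.

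In the fixed limma test over 13729 regions, 0 were wider and 0 narrower at an adjusted p under 0.05, and the smallest adjusted p was 0.668. At an unadjusted p under 0.05 there were 242 regions, 131 of them wider. The median log2 change was 0.14. Groups did not overlap in 131 wider and 83 narrower regions, together 214 (1.56%). This is below the 3.57% that 8 exchangeable libraries would give, a value that does not allow for the 2 sets. Of the 30 arrangements within the 2 sets this was the highest (highest other 130, median of the others 28), a count made after the data were examined. With the 2 sets of libraries as a term and each library centred on its median width, a fit added after the data were examined, limma called 5 regions wider and 22 narrower. These 27 included 7 of the 10 narrower and 3 of the 10 wider regions named above, with the regions on chromosomes 16 (79631402 to 79635998), 4, 14 and 2 (43451304 to 43454922) among the narrower. Of the 3 regions that passed with the replicate block, only that on chromosome 16 passed here too (limma adjusted p = 0.0352). Those on chromosome 5 (limma adjusted p = 0.0836) and chromosome X (39953325 to 39957156, limma adjusted p = 0.124) did not. Centring moved the median log2 change from 0.10 to -0.01, and without it the same model called 0 regions (2204 at an unadjusted p under 0.05, 1758 of them wider). The centred fit called 0 regions without DMSO 1, DMSO 4, DMSO 5 or KDM5-C70 3, 1 without DMSO 3, 13 without DMSO 2, 34 without KDM5-C70 2 and 100 without KDM5-C70 1, and without the variance trend it called 2.

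Within the 5 libraries alone, more regions separated by treatment than by any other pair, but 1 other pair came close. Of 22544 regions called in all 5, both KDM5-C70 libraries were wider than all 3 DMSO libraries in 7890 and narrower in 1717, together 42.61% where chance gives 20%. The highest count of wider regions for any other pair of the 5 was 3772 (DMSO 3 with KDM5-C70 3). DMSO 4 and 5 against the other 3 gave 581 wider and 7195 narrower, and 6 pairs, this one included, had more narrower regions than KDM5-C70 2 and 3. Region ends moved outwards by a median of 54.8 bp on the left and 54.2 bp on the right in KDM5-C70 2 and 3, over 20863 regions with a single interval in each of the 5, while the inner width changed by a median of -37.3 bp. The ends moved further, and inwards, in DMSO 4 and 5 (-62.8 and -61.7 bp), and the inner width fell by more in 3 other pairs, with a change of -64.7 bp in DMSO 4 with KDM5-C70 2, so these shifts do not stand out from other pairs in size. In 37.4% of these regions the outer width was larger and the inner width smaller with KDM5-C70, and in at most 30.4% for another pair. The number of limma calls depended on which regions were tested. Over the 22544 regions there were 0 calls (smallest adjusted p 0.0617), and 5 wider and 32 narrower after centring. Over the 13729 regions called in all 8 there were 480 wider and 109 narrower, and 77 wider and 136 narrower after centring. No other pair of the 5 libraries gave a call in any of these fits. That is 1 of 10 pairs, the lowest share that 10 pairs allow, so chance is not excluded.

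Few regions were called in every library of 1 group and in none of the other. The region on chromosome 2 from 98334937 to 98335620 was called in all 3 KDM5-C70 libraries and no DMSO library, with a mean called width of 323 ± 293 bp (SD, n = 3). The 4 regions called in all 5 DMSO libraries and no KDM5-C70 library lay on chromosome 2 (43445743 to 43447459, 809 ± 585 bp), chromosome 19 (46148703 to 46149628, 444 ± 61.8 bp), chromosome 6 (36726482 to 36726972, 354 ± 113 bp) and chromosome 17 (18553496 to 18553728, 199 ± 18.7 bp; SD, n = 5 for each). Of the 56 splits of the libraries, 38 gave at least 1 region of the first kind and 21 at least 4 of the second, and within the 2 sets 19 and 5 of the 30 arrangements did, so neither count exceeded what other groupings gave. Within the 5 libraries, 1329 regions were called in KDM5-C70 2 and 3 and in none of DMSO 3, 4 and 5, and 342 the other way round. The highest other pair, DMSO 3 with KDM5-C70 3, had 889. The balance turned with other lists, to 894 against 942 with lists of equal length and 123 against 4488 with stricter lists, where 123 was the lowest of the 10 pairs. Of the 1329, KDM5-C70 1 had 2 and DMSO 1 or 2 had 4, so hardly any were called in the other 3 libraries of either group. Other kinds recurred there more often. Of 3136 regions called in only another pair of the 5, 166 were called in those 3 libraries, 95 of them in KDM5-C70 1. Of the 342, 90 were.

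The 5 widest merged regions overlapped between the groups. On chromosome 8, the region from 128746633 to 128751377 had a called width of 3768 ± 1141 bp (SD, n = 3) with KDM5-C70 and 3964 ± 361 bp (SD, n = 5) with DMSO. On chromosome 10, the region from 104401671 to 104406184 had 3523 ± 199 bp and 3790 ± 610 bp. On chromosome 7, the region from 92462003 to 92466157 had 3178 ± 392 bp and 3794 ± 596 bp. Within both sets KDM5-C70 lay below DMSO there. KDM5-C70 1 had 2727 bp, against 3928 and 2737 bp in DMSO 1 and 2. KDM5-C70 2 and 3 had 3438 and 3370 bp, against 4059 to 4127 bp in DMSO 3, 4 and 5. The other regions did not separate within both sets. On chromosome 6, the region from 15244978 to 15250293 had 3516 ± 1146 bp and 3543 ± 1187 bp. On chromosome 5, the region from 180615594 to 180619642 had 3503 ± 172 bp and 3503 ± 301 bp. None of these 5 passed the limma threshold.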

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

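The search for single libraries that stand apart was fixed before the data were examined, and by chance it marks about 5% of the groups it is run on. It was run on 36 groups of DMSO values and marked 4. DMSO 3 had 26 regions of at least 4 kb, while the other 4 DMSO libraries had 6 to 11. In the region on chromosome 2 from 43451304 to 43454922, DMSO 2 had a called width of 3057 bp and the other DMSO libraries 3470 to 3555 bp. In the region on chromosome 5 from 88176066 to 88180395, DMSO 3 had 3590 bp and the others 1929 to 2271 bp. In the region on chromosome 7 from 92462003 to 92466157, DMSO 2 had 2737 bp and the others 3928 to 4127 bp. In the first 2 of these regions every KDM5-C70 library lay below every DMSO library, which follows from how they were chosen.

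DMSO 3 also listed 7 regions on sequences named for Drosophila, 3633 bp in all, and the other 7 libraries listed 0. These regions were outside every comparison above.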

How the results depend on the processing

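The inner share was added after the data were examined, as were all settings that use the 2 sets of libraries, the fits within the 5 libraries, the alternatives of the Jaccard difference and the lists kept by width. Values are KDM5-C70 minus DMSO unless they are counts, and unless a reason is given the cause of a change was not tested. With the stricter lists the difference in the number of regions turned to -9938 and in covered length to -10.6 Mb (exact permutation p = 0.0714 for both, and within sets 0.0333 by absolute differences and 0.0667 with the smaller tail doubled), in median width to -168 bp and in broad regions to -8.80 (both exact permutation p = 0.0357), and the Jaccard difference rose to 0.158 (1-sided exact permutation p = 0.0179). These lists rest on the authors' q-values, which follow the regions poorly and passed 5 in fewer KDM5-C70 regions (4575 ± 2155) than DMSO regions (14513 ± 5102; SD, n = 3 and 5). With inner segments only, the median width differed by -88.4 bp and the covered length by -0.64 Mb (exact permutation p = 0.0357 and 0.929). Counting regions of at least 2 kb turned the difference in broad regions to 901 (exact permutation p = 0.393), and no library had a region of 10 kb. Leaving out 1 library at a time, the number differed by -396 (without KDM5-C70 3) to 9590, the median width by -11.4 (without KDM5-C70 2) to 27.1 bp, the covered length by 0.386 to 11.02 Mb, the broad regions by -6.17 to -1.17 and the Jaccard difference by 0.00022 to 0.0653. The inner share then differed by -13.7 to -11.7 percentage points, with exact permutation p of 0.0571 or 0.0952, the smallest that fewer libraries allow. The fixed width test called 0 regions without any 1 library, 1 with stricter lists and 2 with lists of equal length, where 10 and 934 regions were left to test. It called 27 with the sets as a term and centred, 147 in inner segments with that term (1 wider and 146 narrower), 37 in the 5 libraries after centring, and 589 over the regions called in all 8, with 213 there after centring. The fit with sets and centring called 0 without centring, 2 without the variance trend, 117 in inner segments and 0 to 100 without 1 library. In all, 35 width fits were run, 17 of them fixed beforehand. Regions called in every KDM5-C70 and no DMSO library numbered 1, and 0 with stricter lists or a largest -log10 q-value of at least 5, 16 with lists of equal length, 7 in inner segments, 4 when joined within 1000 bp, 4 when 50% of the region was required and 1 to 1325 without 1 library. The highest of these came without KDM5-C70 1. The reverse kind numbered 4, and 926, 57, 65 and 7 with stricter lists, equal lists, inner segments and the 50% rule, and 4 to 50 without 1 library. Regions called in KDM5-C70 2 and 3 and not in DMSO 3, 4 and 5 numbered 1329, and 123 with stricter lists, 894 with equal lists, 739 with the widest regions, 454 with the q-value limit and 1556 to 6785 without 1 library. The reverse kind numbered 342, and 4488 with stricter lists, 942 with equal lists, 697 with the widest regions, 1126 in inner segments and 521 to 1224 without 1 library. Fewer libraries must meet the condition in each count without 1 library. With replicate numbers 1 to 3 as a block, the inner share differed by -13.6 percentage points (exact sign-flip permutation p = 0.25, the smallest 3 pairs allow), the width test called 2 wider and 8 narrower, 10 in all, and the 2 kinds of regions called in 1 group numbered 8 and 14; the block changed no other call. Deviations of libraries with the same number correlated at 0.37, -0.31 and 0.32, so the numbers share no clear pairing, and the number inside the DMSO 3 list is 4. Of the 20 regions named for width, 0 reversed under 13 alternatives each. Only the fits with centring could have reversed one, since the regions were chosen for groups that do not overlap. The 8 that leave out a library, the block, the fit without the variance trend and the sets without centring could not. Of the 20, 10 passed the threshold with the sets as a term and centring, and 3 with the block. Region centres near transcription start sites, promoters and gene lists were not run, because the gene table is of another genome build. Equal lists fix the number of regions, so that value was not compared. Depth is unknown and limits every statement on regions that were not called.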

Other observations

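Of the tests in this part, those on the width changes shared by the 2 sets and on the recurrence of the regions called in the 5 libraries were written down before their results were seen. Counts under other groupings were planned for the results fixed beforehand, and the remaining tests, lists cut by width and distances included, were chosen only after the results were seen. In the 5 libraries DMSO 3, 4, 5 and KDM5-C70 2 and 3, the regions that limma called after centring were mostly narrower with KDM5-C70 (32 of 37). The region on chromosome 5 from 88176066 to 88180395 had a called width of 474 ± 22.6 bp (SD, n = 2) with KDM5-C70 and 2664 ± 805 bp (SD, n = 3) with DMSO, a centred log2 change of -2.64 (SE 0.18, limma adjusted p = 0.0268). The region on chromosome 10 from 63660492 to 63664400 had 793 ± 147 bp against 2941 ± 437 bp, and that on chromosome 6 from 138187607 to 138190760 had 706 ± 110 bp against 2265 ± 510 bp. Among the 5 that widened, the region on chromosome 10 from 74020122 to 74022380 had 2139 ± 170 bp against 672 ± 151 bp, and that on chromosome 6 from 69282676 to 69286622 had 3192 ± 14.1 bp against 1307 ± 228 bp. These examples were chosen after their values were seen, and without centring limma's adjusted p was 0.0617 for each of them. Of 5023 regions at an unadjusted p under 0.05, 4293 were wider without centring, and of 3631 after centring 1653 were wider.

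Chromosomes differed in limma's camera test with the sets of libraries as a term. Relative to regions elsewhere, the 451 regions on chromosome X (median log2 change -0.001, adjusted p = 0.00101) and the 390 on chromosome 14 (median 0.002, adjusted p = 0.00124) were narrower with KDM5-C70, against a median of 0.10 over all regions. With an estimated correlation neither call held (adjusted p = 0.997 for both).

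The first pattern is the fall of the 8 lists into 3 and 5 libraries. Cutting every list to its 15323 widest regions left the mean Jaccard index 0.164 higher within the 2 sets than between them, which argues against the number of regions as the whole source. The cut lists still covered 12.9 to 25.3 Mb, and the index is counted in bases, so covered length stays open as a source. A processing batch, a difference in depth and separate cultures stay open and were not tested, since the labels name no batch, the numbers inside the lists (4, 5 and 6 for DMSO 3, 4 and 5) do not give one, and depth is unknown.

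The second pattern is the smaller inner share with KDM5-C70. List length alone is argued against, because with the widest 15323 regions of each list the lowest DMSO share stayed 6.14 percentage points above the highest KDM5-C70 share. Weaker enrichment in the KDM5-C70 libraries cannot be told apart from treatment, because depth is unknown. KDM5-C70 2 and 3 covered at least 0.435 Mb more than every DMSO library of their set, which runs against it, but the authors' median fold enrichment was lower in every KDM5-C70 library (2.388 to 2.672) than in every DMSO library (2.831 to 3.1), which goes with it. Fold enrichment is not comparable between libraries of unknown depth, so neither settles it. An effect of the inhibitor, such as spread of the mark from the centre of a region, may account for a share that was lower within both sets (exact permutation p = 0.0333 by absolute differences, 0.0667 with the smaller tail doubled), but caller cutoffs that differ between libraries would give the same picture and were not tested.

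The third pattern is the set of 1329 regions shared by KDM5-C70 2 and 3 and not called in DMSO 3, 4 and 5. They were small (median called width 435 bp) and lay a median of 79.9 kb from the nearest region called in all 8 libraries, but so were regions called in only another pair (343 bp and 69.2 kb). They differed from those in recurrence, with 5 of the 1329 called in the first set of 3 libraries, against 166 of 3136. With the 5 lists cut to their 28195 widest regions the count was 739, still 1.22 times that of the highest other pair (605), which argues against list length as the whole cause of the count. The balance is another matter: against 697 the other way round the ratio was 1.06 (95% exact binomial interval 0.955 to 1.18), down from 3.89 with full lists, so list length could account for the excess over the reverse kind. With stricter lists the count was 123, the lowest of the 10 pairs. Spread from existing regions could account for part of them and stays open: 5.12% lay within 5 kb of a region called in all 8, against 3.89% for other pairs (odds ratio 1.33, 95% interval 0.968 to 1.82, Fisher's exact p = 0.0741), and 8.43% within 5 kb of a region called in all 5, against 8.29% (odds ratio 1.02, 95% interval 0.8 to 1.29, Fisher's exact p = 0.906). For regions called in all 8, the prediction as first written read this result against spread. It was reread as undecided after the values were seen, because the 95% interval is wide. Of the 342 regions of the reverse kind more lay within 5 kb, 10.8% of a region called in all 8 and 18.7% of one called in all 5. Only 1.28% lay on chromosome 19, against 3.44% for other pairs (odds ratio 0.363, 95% interval 0.203 to 0.612, Fisher's exact p = 2.53e-05), and whether they are background calls or new sites of the mark was not tested.

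Other groupings of the 8 libraries were counted for each result across regions. For regions called in every library of 1 group only, 38 of 56 splits gave at least the 1 region of KDM5-C70 (highest other 853) and 21 of 56 at least the 4 of DMSO (highest other 5362), so chance is not excluded for either, nor is it within the 2 sets (19 and 5 of 30 arrangements). For the fixed width test the count was 0, which all 56 splits must reach, so the comparison says nothing on chance. The highest other, 10652, came from the split into the 2 sets, which points to a structure of the samples but restates the first pattern, since the sets were read from the same lists. With the sets as a term and without centring all 30 arrangements gave 0 calls, which says nothing on chance either. With centring, only 1 of the 30, the real one, gave as many as 27 (highest other 4). That is the lowest share that 30 arrangements allow, so chance is not excluded for that count. This fit was also chosen after the data were examined from 35 width fits in all, and the count did not survive several of the settings above.

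If KDM5-C70 changed the same widths in both sets, which have no library in common, the changes would correlate between them. Across the 13729 regions, which are not independent replicates, Pearson's r was 0.124 and Spearman's rho 0.101. Only 1 of 30 arrangements, the real one, reached that r, but the highest other was 0.113, so a shared effect of treatment on width may exist. Noise in each set also lowers r, so r does not give the size of such an effect. Of the 37 regions called in the 5 libraries after centring, 27 were measured in all 8, and KDM5-C70 1 lay beyond both DMSO 1 and 2 in the same direction in 12 (44.4%) and in the opposite direction in 8, against 35.8% in the same direction for other regions (odds ratio 1.43, 95% interval 0.612 to 3.28, Fisher's exact p = 0.422). By the rule written down beforehand, a Fisher's exact p of this size counted against recurrence, so the prediction failed as written. After the values were seen the result was reread as undecided, because the 95% interval is wide and includes 1. With 27 regions the test does not settle whether they recur.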
